A study of Rattus norvegicus with 20 samples.

How the data were processed

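Expression was measured on 20 Affymetrix Rat Gene 2.0 arrays, 1 per well of INS-1 cells, with 5 arrays for each of 4 title words (DMSO, IAPP, C4BPD and C4BP). Per the series description, 5 clones had been kept apart over 10 passages, each well of a 12-well plate received 100000 cells, treatment began about 48 h later, and RNA was taken 10 h into it. The sample fields add doses of 300 ug/ml for IAPP and for C4BP beside the molar doses of the series description.

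The deposited values are intensities, normalized and summarized per probe set by the authors on a linear scale. Affymetrix Expression Console is named in the submitters' processing notes, and its version, the normalization algorithm and the annotation are not given in the sources used here. The intensity scale was read from the values, which are all above 0 and run from 4.729 to 18573.71. The array medians, in replicate order 1 to 5, were 174, 176.24, 178.64, 175.68 and 178.98 in DMSO. In IAPP they were 172.79, 181.23, 175.44, 182.36 and 177.56. In C4BPD they were 173.58, 177.09, 174.67, 180.58 and 178.74, and in C4BP 170.01, 181.19, 175.43, 179.4 and 181.73. No 2 arrays had identical values. The normalization algorithm stays unknown, since the deposited intensities were not compared with scanner files, and no detection p-values were used. The number of arrays limits the precision.

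Groups were taken from the title of each sample. The title and the sample description give the same word and number, and each number from 1 to 5 occurs once per word. The separate treatment field matches the title word in 2 of the 10 arrays titled IAPP or DMSO, and in 3 of all 20 when C4BP is read as C4BP with IAPP and C4BPD as C4BP alone. The titles were preferred before the data were examined, as were the model, the comparisons, the gene lists, the rule for named genes and the alternatives. Grouping by the treatment field was run as an alternative.

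Of 36685 probe sets, 190 controls were left out. Gene names came from the GEO platform annotation, in which 18511 probe sets carry 1 gene symbol, 575 several and 17599 none. Each gene was represented by its probe set with 1 symbol and, for the 291 genes with more than 1, by the brightest over all 20 arrays, which gave 18166 genes. Probe sets with several symbols or none were tested separately. The log2 of each intensity was taken, with no further normalization and no filter on dim genes. The lowest group means of Smad7, Micalcl, Lrp2bp, Ndst4, Kctd8, Ranbp3l, Stap2, Sidt1, Cytip, Tsx, Defa6, Gba3 and Mir19b2 lay under 7.459 on the log2 scale, the median of all probe sets, and were not shown to be above background. No genome build or coordinates were used.

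One linear model with 4 group means was fitted to all 20 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 15 residual degrees of freedom). It gave 6 pairwise comparisons, the interaction (C4BP minus C4BPD) minus (IAPP minus DMSO) and a moderated F test across the 4 groups. All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Folds are ratios of geometric means, and group levels are arithmetic means of intensity with their SD. Whether the replicate numbers pair the samples was checked on the data alone, by correlating deviations from the group means across genes. In C4BPD vs IAPP all 5 same-numbered pairs correlated over 0.1 (0.152 to 0.305), so the count with the number as a block stands beside that result. In the other 5 comparisons at least 1 pair did not. In C4BP vs IAPP 4 of 5 did (median 0.318), and its block count is given as well. Block counts of every comparison are among the alternatives. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

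Genes are named by a fixed rule. In each comparison these are the 10 largest positive and 10 largest negative log2 differences among genes past the threshold. Where fewer than 10 genes pass, the 10 with the smallest p are named. Added to these are up to 4 members of each called list with the smallest p in the list's direction, and fixed genes, of which Ins1, Ins2, Iapp, Ddit3, Hspa5 and Txnip are reported. Other fixed genes are not analysed here. Beyond about 10 genes, the text gives a selection of those the rule names.

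There were 33 gene lists with 544 members given, written from general knowledge of beta cells, stress responses and lipid synthesis and of the cell types that a culture could hold. The 31 lists with at least 5 measured members were tested with camera (limma) at its preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists within a comparison. Camera with an estimated correlation and fry were run beside it. The 2 other lists, endothelial and blood markers and small nucleolar RNAs, had fewer than 5 measured members and were not tested. For each list the members past the threshold were counted over all genes and adjusted over the list alone. Of 48 list calls, the interaction included, 19 held with an estimated correlation and 29 did not. Fry asks whether a list's members move one way and compares them with no other genes, so its values are given beside the calls and make none.

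The model was tested on simulated data in which known changes were added to random normal values drawn with the mean and SD of each of 18166 genes. It recovered 67.2% of genes simulated at a log2 difference of 0.25, 95.5% at 0.5 and 100% at 1, with 13 false calls among 188. There were 0 calls at the adjusted threshold in the comparison where no change was simulated. Both lists shifted by 0.3 were called and 0 others. The simulated genes were drawn independently of each other, so false list calls from correlated members could not arise and were not tested.

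The alternatives were the replicate number as a block, fixed or random, quantile normalization, centring arrays on their median, leaving out dim genes, limma's trend and robust options, array weights, the mean of a gene's probe sets, all probe sets in place of genes, a fit of the compared groups alone, the treatment field in place of the titles, the other reading of the titles, and leaving out each array and each replicate number in turn. For 2 short lists of pathway genes, camera was accompanied by two-sided exact permutation tests over the 252 splits of the 10 arrays compared, on the mean of the list less the mean of all genes. Chance was addressed with 100 splits of the arrays per comparison, the real one included.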

Results

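Gene expression was measured in INS-1 cells, a rat insulinoma line that makes insulin and serves as a beta-cell model. The cells were challenged with islet amyloid polypeptide (IAPP, or amylin), a beta-cell hormone that forms amyloid, alone or together with C4b-binding protein (C4BP), a plasma inhibitor of complement. Per the series description, IAPP was given at 77 uM and C4BP at 0.6 uM, wells with DMSO (1%), the solvent of IAPP, and wells with C4BP alone served as controls, and RNA was taken after 10 h. The 20 arrays fall into 4 groups of 5 by their titles, which read DMSO, IAPP, C4BPD and C4BP. The last pair of titles is not spelled out. The likely reading, from the 4 conditions of the design and the order in which the samples are listed, is C4BP together with IAPP for wells titled C4BP, and C4BP without IAPP for wells titled C4BPD. A separate treatment field names the same word as the title in 2 of the 10 arrays titled IAPP or DMSO, so every group rests on the titles. Median intensities ran from 170.01 to 182.36, and the log2 values of any 2 arrays correlated across probe sets at 0.994 to 0.998. Replicates are separate samples of cells grown as 5 clones, and the labels do not state that the replicate number is the clone. The number of arrays limits the precision.

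Across all 4 groups, 1426 of 18166 genes (7.85%) differed in limma's moderated F test at an adjusted p under 0.05. Comparisons with DMSO use the same 5 DMSO arrays, so overlaps between them are not independent. The number of genes past the threshold in each comparison is shown in the bar chart of counts.

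**Figure D1:**
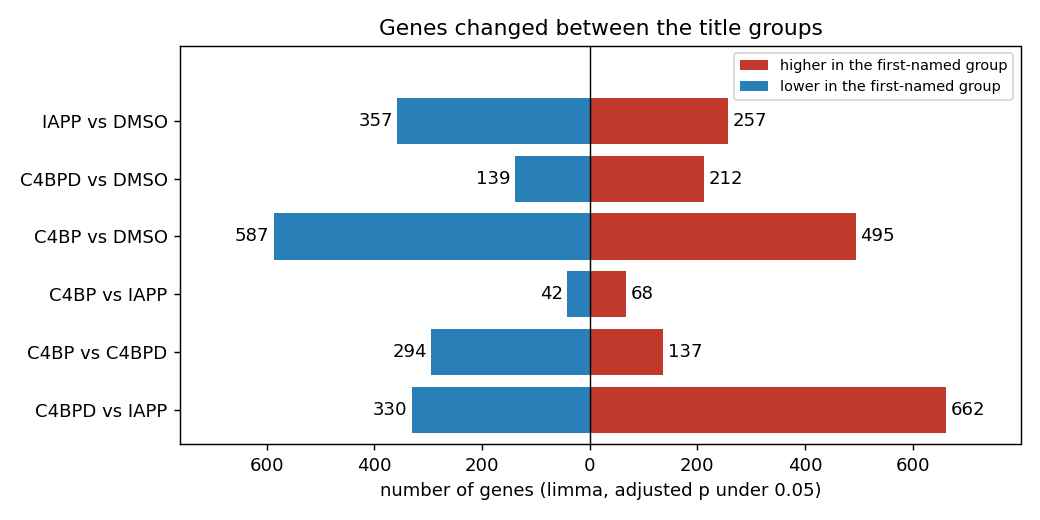
Number of genes higher (right) and lower (left) in the first-named title group, for 6 comparisons of 5 arrays with 5 (limma, adjusted p under 0.05, 18166 genes). The counts run from 110 genes in C4BP vs IAPP (68 higher, 42 lower) to 1082 in C4BP vs DMSO (495 higher, 587 lower).

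What IAPP does to these cells is asked by IAPP vs DMSO. Jun, a subunit of the AP-1 transcription factor (probe set 17808683), rose from an intensity of 328 ± 43.9 in DMSO to 965 ± 183 in IAPP (SD, n = 5 each), a 2.92-fold difference (limma, adjusted p = 1.23e-08). Cpt1a, which brings fatty acids into mitochondria, rose from 1170 ± 112 to 2480 ± 37.5, or 2.13-fold. Trib3, a pseudokinase induced by the transcription factor ATF4, rose 2.52-fold, and Hmox1, the inducible heme-degrading enzyme, rose 1.68-fold. Nr4a1, an immediate early nuclear receptor, fell by 0.85 on the log2 scale, and Vdr, the vitamin D receptor, fell by 0.78.

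In all, 614 genes (3.38%) changed, 257 higher and 357 lower, 6 of them at least 2-fold. Other genes with large rises were the metallothioneins Mt1 and Mt1f (2.78-fold and 2.68-fold), close relatives whose probes were not tested for shared signal, the stress-induced repressor Atf3 (2.13-fold), Chac1, an enzyme that degrades glutathione (1.94-fold), the amino acid transporter Slc1a4 (0.72 on the log2 scale), and Or8h7b, annotated as an olfactory receptor (0.79). The largest falls included Fyb1 (fell by 0.76 on the log2 scale), the phosphodiesterase Pde7b (fell by 0.73), the ER-degradation factor Derl3 (fell by 0.71), the deiodinase Dio2 (fell by 0.70), the kinase Sik1 (fell by 0.68), the lipid transporter Mfsd2a (fell by 0.68) and tissue factor F3 (fell by 0.63).

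ATF4 targets and integrated stress response genes rose as a list: 12 of 23 measured members were higher, 0 lower and 11 did not pass, with 13 higher adjusted over the list alone (camera adjusted p = 1.44e-19). Besides Trib3 and Chac1, Aars1, an alanyl-tRNA synthetase, rose by 0.36 on the log2 scale and Psat1, of serine synthesis, by 0.33. The NRF2 and metal response list also rose, with 8 of 16 higher, 0 lower and 8 not passing, and 11 higher adjusted over the list alone (camera adjusted p = 4.88e-18). Its members Srxn1, which repairs oxidized peroxiredoxins, and Slc30a1, a zinc exporter, rose by 0.30 and 0.62 on the log2 scale. Cholesterol synthesis and uptake genes fell, with 0 of 19 higher, 7 lower and 12 not passing, and 14 lower adjusted over the list alone (camera adjusted p = 3.48e-17). Hsd17b7, Idi1 and Msmo1, enzymes of sterol synthesis, fell by 0.52, fell by 0.38 and fell by 0.26 on the log2 scale, and Insig1, a sterol sensor partner, fell by 0.30. Fatty acid synthesis fell, with 0 of 13 higher, 4 lower and 9 not passing, and 1 higher and 7 lower adjusted over the list alone (camera adjusted p = 4.37e-06). Srebf1, the transcription factor of that pathway, fell by 0.31, and the desaturase Scd2 fell by 0.30. These 4 lists kept their calls with an estimated correlation.

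The list of ER chaperones and unfolded protein response genes had 0 of 24 members higher, 9 lower and 15 not passing, and 17 lower adjusted over the list alone (camera adjusted p = 3.59e-14; adjusted p = 0.107 with an estimated correlation). Creld2 and Sdf2l1, both ER-resident, fell by 0.39 and fell by 0.38 on the log2 scale. In the list of beta-cell identity and secretion, 0 of 23 were higher, 3 lower and 20 did not pass, with 4 lower adjusted over the list alone (camera adjusted p = 0.00102; adjusted p = 0.108 with an estimated correlation). The 3 were the transcription factors Isl1 (-0.18) and Mafa (-0.26) and the glucose transporter Slc2a2 (-0.11). In hypoxia and glycolysis, 0 of 13 passed and 1 was lower adjusted over the list alone (camera adjusted p = 0.033; adjusted p = 0.251 with an estimated correlation). That call was lost without DMSO 3 (0.101), IAPP 2 (0.069), IAPP 4 (0.0632) or IAPP 5 (0.0727). Immediate early genes went both ways, with 4 of 30 higher, 7 lower and 19 not passing, and 5 higher and 9 lower adjusted over the list alone (camera adjusted p = 0.0752). Ddit3, the stress factor CHOP, rose from 660 ± 60.2 to 909 ± 98.1 (adjusted p = 0.00118). Ins1, Ins2 and the cells' own Iapp did not pass, at -0.04, -0.14 and -0.08, nor did Hspa5 (-0.10) and Txnip (0.09). The count was 405 without IAPP 4, 235 without all arrays of number 4, and 437 (156 higher, 281 lower) with arrays centred on their median. Of the 39 named genes past the threshold, 5 (Acaca, Edem1, Isl1, Mafa and Slc2a2) lost their calls in 4 to 10 of the fits that each left out 1 array, at adjusted p up to 0.121, these and Acss2 under another scaling or fit (up to 0.131), and 9, among them Fyb1, Srebf1 and Scd2, without all arrays of some number (up to 0.249).

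**Figure D2:**
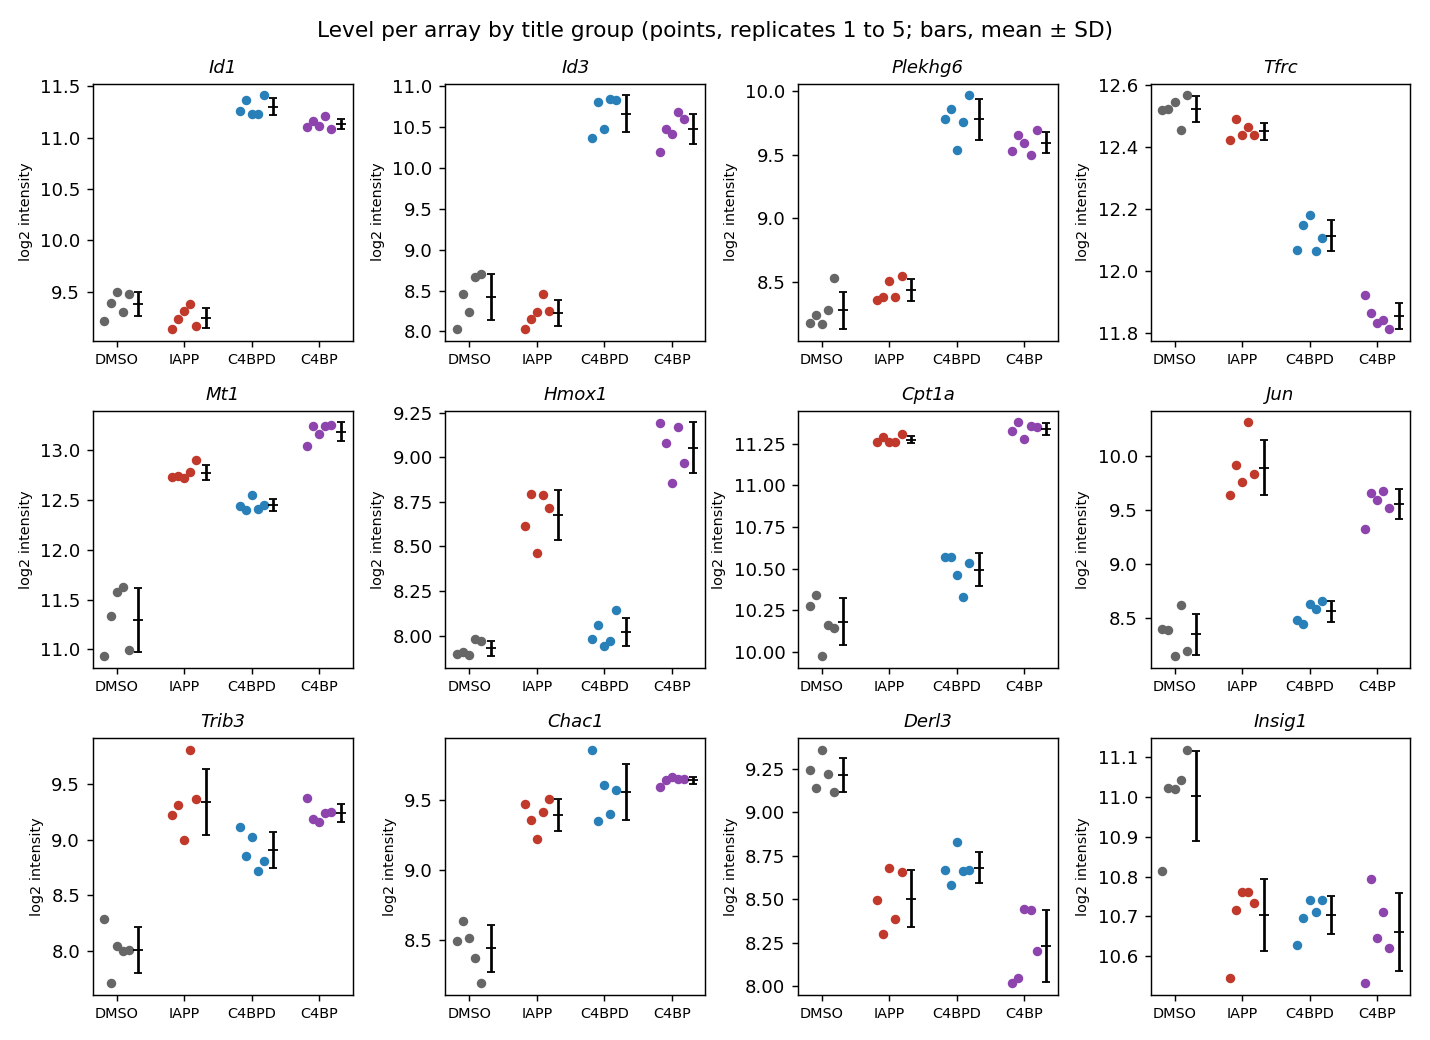
Log2 intensity of 12 genes in each array (points, y axes not starting at 0) with the mean and SD of each title group of 5, for genes chosen after their values were seen. Id1 averaged 666 in DMSO and 608 in IAPP but 2530 in C4BPD and 2250 in C4BP on the linear scale, while Jun averaged 328 and 378 in DMSO and C4BPD but 965 and 756 in IAPP and C4BP.

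The question of what C4BP does on its own is addressed by C4BPD vs DMSO, under the likely reading of the titles. The largest rises were in Id1 and Id3, inhibitors of helix-loop-helix transcription factors. Id1 (probe set 17767420) rose from 666 ± 53.4 to 2530 ± 148 (SD, n = 5 each), 3.79-fold (limma, adjusted p = 8.93e-15), and Id3 rose from 348 ± 66 to 1640 ± 244, 4.74-fold. Plekhg6 rose 2.83-fold, and the inhibitory SMAD protein Smad7 rose 1.69-fold. Mt1 rose 2.22-fold and Chac1 2.17-fold. Ankrd37, a hypoxia-induced gene, fell by 0.65 on the log2 scale, and the water channel Aqp5 fell by 0.66.

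Altogether 351 genes (1.93%) changed, 212 higher and 139 lower, 6 of them at least 2-fold. Mt1f rose 2.01-fold, Trib3 1.86-fold, Micalcl by 0.82 on the log2 scale and Slc1a4 by 0.78. Falls included Derl3 (fell by 0.53), the ion cotransporter Slc12a2 (fell by 0.49), the collagen prolyl hydroxylase subunit P4ha1 (fell by 0.48), the glycolysis regulator Pfkfb3 (fell by 0.47), Rnd1 (fell by 0.46), Lrp2bp (fell by 0.46) and the muscarinic receptor Chrm4 (fell by 0.45).

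ATF4 targets rose, with 8 of 23 higher, 0 lower and 15 not passing, and 11 higher adjusted over the list alone (camera adjusted p = 1.24e-13). Psat1 and Aars1 rose by 0.41 and 0.29 on the log2 scale. In the NRF2 and metal response, 3 of 16 were higher, 0 lower and 13 did not pass, with 6 higher adjusted over the list alone (camera adjusted p = 4.17e-07). Slc30a1 rose by 0.67, and Nqo1, a quinone reductase, by 0.45. NF-kB and inflammatory genes had 4 of 26 higher, 0 lower and 22 not passing, and 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0063). The chemokine Cxcl11 rose by 0.34, while Cxcl10 (0.32) and the NF-kB subunit Relb (0.28) passed but lost their calls in other fits, Relb with centred arrays (adjusted p = 0.0597) and without all arrays of number 2 or 3 (up to 0.103). Cholesterol genes fell, with 0 of 19 higher, 5 lower and 14 not passing, and 14 lower adjusted over the list alone (camera adjusted p = 2.03e-14). Msmo1, Dhcr7, Mvd and Insig1 fell by 0.28, fell by 0.26, fell by 0.25 and fell by 0.30 on the log2 scale. The ER chaperone list fell, with 0 of 24 higher, 7 lower and 17 not passing, and 18 lower adjusted over the list alone (camera adjusted p = 4.97e-17). Creld2 and Sdf2l1 each fell by 0.39. Hypoxia and glycolysis genes fell, with 0 of 13 higher, 4 lower and 9 not passing, and 6 lower adjusted over the list alone (camera adjusted p = 3.7e-05). All 6 lists kept their calls with an estimated correlation.

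The other lists with calls did not keep them. Fatty acid synthesis had 0 of 13 past the threshold and 3 lower adjusted over the list alone (camera adjusted p = 0.0218; adjusted p = 0.229 with an estimated correlation). Immediate early genes had 5 of 30 higher, 0 lower and 25 not passing, and 6 higher adjusted over the list alone (camera adjusted p = 0.00717; adjusted p = 0.17 with an estimated correlation). Among these Phlda1, Jund and Klf6 rose by 0.56, 0.32 and 0.25 on the log2 scale. Mitosis had 0 of 18 past the threshold and 0 adjusted over the list alone, with a mean of 0.07 (camera adjusted p = 3.7e-05; adjusted p = 0.252 with an estimated correlation). Acinar and duct markers had 0 of 13 in either count, with a mean of -0.084 (camera adjusted p = 0.0339; adjusted p = 0.424 with an estimated correlation and 0.0508 with quantile normalization). Without single arrays 3 lists lost their calls: fatty acid synthesis without DMSO 4 (0.08) or DMSO 5 (0.0696), immediate early genes without C4BPD 1 (0.0955), and acinar and duct markers without DMSO 1 (0.0812), DMSO 5 (0.135), C4BPD 2 (0.0657) or C4BPD 5 (0.0951). Ins1, Ins2, Iapp and Ddit3 did not pass, at 0.03, -0.03, 0.00 and 0.01, nor did Txnip at -0.08. The count was 233 without DMSO 5, 230 without C4BPD 2, 217 without C4BPD 5, 151 without all arrays of number 5, 223 (135 higher, 88 lower) with centred arrays, 320 (170 higher, 150 lower) with quantile normalization, 644 with array weights, 226 over all probe sets and 208 in a fit of the compared groups alone. Of the 40 named genes past the threshold, 4 (Defa6, Hspa5, Nfkbiz and Slc2a1) lost their calls in 4 to 9 of the fits that each left out 1 array, at adjusted p up to 0.132, 5 (Hspa5, Slc2a1, Relb, Arc and Chrm4) under another scaling or fit (up to 0.137), and 14, among them Cxcl10, Klf6, Jund, Insig1, Mvd, P4ha1 and Lrp2bp, without all arrays of some number (up to 0.267).

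The combined treatment, under the likely reading, is set against the solvent in C4BP vs DMSO. Id3 rose from 348 ± 66 to 1430 ± 179 (SD, n = 5 each), 4.15-fold (limma, adjusted p = 1.12e-09), and Id1 3.39-fold. Mt1 rose from 2560 ± 555 to 9310 ± 571, 3.71-fold. Jun rose 2.31-fold, Cpt1a 2.23-fold and Hmox1 2.18-fold. Derl3 fell by 0.98 on the log2 scale, and Dusp6, a phosphatase of ERK kinases, fell by 0.87.

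The change took in 1082 genes (5.96%), 495 higher and 587 lower, 10 of them at least 2-fold. Mt1f rose 3.58-fold, Plekhg6 2.49-fold, Trib3 2.36-fold and Chac1 2.3-fold. Other falls were in Fyb1 (fell by 0.92), Tmem215 (fell by 0.88), Aqp5 (fell by 0.83), Nr4a1 (fell by 0.78), Mfsd2a (fell by 0.77), Ankrd37 (fell by 0.76), Vdr (fell by 0.73) and the heparan sulfate enzyme Ndst4 (fell by 0.72).

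Cholesterol genes had 0 of 19 higher, 14 lower and 5 not passing, and 15 lower adjusted over the list alone (camera adjusted p = 3.59e-21). Hsd17b7, Msmo1, Idi1 and Mvd fell by 0.62, fell by 0.45, fell by 0.45 and fell by 0.35 on the log2 scale. The ER chaperone list had 0 of 24 higher, 15 lower and 9 not passing, and 20 lower adjusted over the list alone (camera adjusted p = 3.64e-24). Creld2 fell by 0.57, Sdf2l1 fell by 0.55, and Hspa5, the chaperone BiP, fell by 0.21 (adjusted p = 0.000106). For fatty acid synthesis, 0 of 13 were higher, 8 lower and 5 did not pass, with 1 higher and 9 lower adjusted over the list alone (camera adjusted p = 6.07e-07). Scd2 and Srebf1 fell by 0.44 and fell by 0.31. The hypoxia and glycolysis list had 0 of 13 higher, 4 lower and 9 not passing, and 7 lower adjusted over the list alone (camera adjusted p = 2.62e-06), with Pfkfb3 the next after Ankrd37 (fell by 0.71). The NRF2 and metal response rose, with 11 of 16 higher, 0 lower and 5 not passing, and 11 higher adjusted over the list alone (camera adjusted p = 3.82e-21). Nqo1 rose by 0.66, and Gclm, of glutathione synthesis, by 0.34. ATF4 targets had 10 of 23 higher, 0 lower and 13 not passing, and 13 higher adjusted over the list alone (camera adjusted p = 4.65e-14). Psat1 rose by 0.45 and Aars1 by 0.40. These 6 lists kept their calls with an estimated correlation.

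Among p53 targets, 0 of 13 were higher, 1 lower and 12 did not pass, with 2 lower adjusted over the list alone (camera adjusted p = 0.00306; adjusted p = 0.077 with an estimated correlation). Beta-cell identity and secretion had 0 of 23 higher, 4 lower and 19 not passing, and 5 lower adjusted over the list alone (camera adjusted p = 0.00306; adjusted p = 0.133 with an estimated correlation). Slc2a2 fell by 0.14 on the log2 scale, and the granule zinc transporter Slc30a8 fell by 0.17. Ins1, Ins2 and Iapp did not pass, at -0.04, -0.12 and -0.09, nor did Ddit3 (0.17) and Txnip (-0.28). The count was 663 in a fit of the compared groups alone and 615 without all arrays of number 5. Of the 43 named genes past the threshold, 5 (Plk2, Nkx2-2, Mafa, Slc2a1 and Vegfa) lost their calls in 1 to 9 of the fits that each left out 1 array, at adjusted p up to 0.132, these and Fads1, Slc2a2 and Slc30a8 under another scaling or fit (up to 0.161), and 8, among them Slc30a8, without all arrays of some number (up to 0.259).

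Whether C4BP alters the cells' state in the presence of IAPP is the question behind C4BP vs IAPP. Id3 rose from 301 ± 33.1 in IAPP to 1430 ± 179 in C4BP (SD, n = 5 each), 4.74-fold (limma, adjusted p = 8.35e-10). Id1 rose from 608 ± 42.2 to 2250 ± 79.6, 3.71-fold, and Plekhg6 2.24-fold. Tfrc, the transferrin receptor that imports iron, fell from 5600 ± 106 to 3710 ± 109 (log2 scale: fell by 0.60; adjusted p = 1.18e-09). The receptor Acvr1c, of the activin family, and Smad9, a SMAD protein of the BMP pathway, rose by 0.63 and 0.53 on the log2 scale. Atf3, raised in IAPP vs DMSO, was at -0.68 (adjusted p = 0.0179), a call lost without IAPP 2 (adjusted p = 0.0653), with array weights (0.0681), in a fit of the compared groups alone (0.159) and without all arrays of number 1, 2, 4 or 5 (up to 0.209).

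Here 110 genes (0.606%) changed, 68 higher and 42 lower, 3 of them at least 2-fold. Micalcl rose by 0.77 on the log2 scale, the transcription factor Barhl1 by 0.61, Id4 by 0.49, Kctd8 by 0.48 and the bombesin-like receptor Brs3 by 0.47. Ankrd37 fell by 0.56, Pfkfb3 fell by 0.47, Narf fell by 0.41 and Ranbp3l fell by 0.37. The NRF2 and metal response list had 2 of 16 higher, 0 lower and 14 not passing, and 5 higher adjusted over the list alone (camera adjusted p = 7.55e-07), and kept its call with an estimated correlation. Nqo1 and Hmox1 were at 0.42 and 0.38, where Hmox1 lost its call in a fit of the compared groups alone (adjusted p = 0.116) and without all arrays of number 1, 2 or 4 (up to 0.089), and Mt1, at 0.41, did not pass (adjusted p = 0.0746).

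The remaining list calls were lost with an estimated correlation. Hypoxia and glycolysis had 0 of 13 higher, 2 lower and 11 not passing, and 3 lower adjusted over the list alone (camera adjusted p = 4.45e-05; adjusted p = 0.0616 with an estimated correlation). ER chaperones had 0 of 24 past the threshold and 1 lower adjusted over the list alone (camera adjusted p = 8.67e-11; adjusted p = 0.191 with an estimated correlation), with Hspa5 at -0.11 and Derl3 at -0.27. Cholesterol synthesis had 0 of 19 higher, 1 lower and 18 not passing, and 1 lower adjusted over the list alone (camera adjusted p = 5.38e-05; adjusted p = 0.191 with an estimated correlation). For p53 targets, 0 of 13 passed and 2 were lower adjusted over the list alone (camera adjusted p = 0.00237; adjusted p = 0.163 with an estimated correlation), with Phlda3 at -0.23. Mitosis had 0 of 18 past the threshold and 0 adjusted over the list alone (camera adjusted p = 7.55e-07; adjusted p = 0.214 with an estimated correlation), with the cyclin Ccnb1 at 0.13. The ATF4 list had 0 of 23 higher, 1 lower and 22 not passing, and 2 higher and 3 lower adjusted over the list alone, and was not called (camera adjusted p = 0.99). Ddit3 did not pass at -0.29 (adjusted p = 0.102), nor did Ins1, Ins2 and Iapp, at 0.00, 0.02 and -0.01. The count was 66 without IAPP 2, 58 without IAPP 3, 67 without IAPP 4, 64 without C4BP 4 and 73 without C4BP 5. It was 18 without all arrays of number 4, 70 (49 higher, 21 lower) with centred arrays and 70 over all probe sets. With dim genes left out it was 200, in a fit of the compared groups alone 33, and with the replicate number as a fixed block 352. Of the 23 named genes past the threshold, 6 (Atf3, Ak4, Gba3, Txnip, Tac1 and Msmo1) lost their calls in 1 to 9 of the fits that each left out 1 array, at adjusted p up to 0.137, these and Narf and Hmox1 under another scaling or fit (up to 0.223), and 12, among them Nqo1, Id4, Pfkfb3, Narf and Ranbp3l, without all arrays of some number (up to 0.338).

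**Figure D3:**
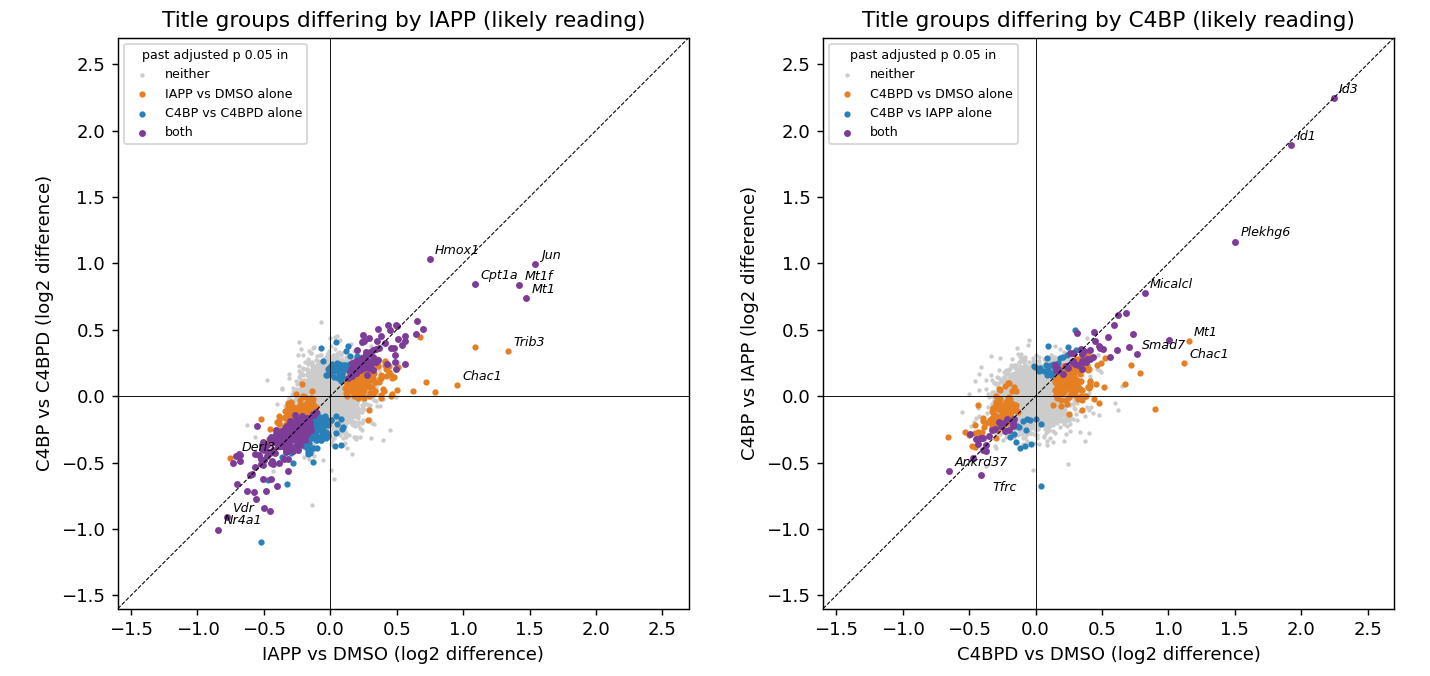
Log2 difference of each of 18166 genes in 2 comparisons that share no array, IAPP vs DMSO against C4BP vs C4BPD (left) and C4BPD vs DMSO against C4BP vs IAPP (right); colours mark genes past an adjusted p under 0.05 and the labelled genes were chosen after their values were seen. Genes past the threshold in both comparisons lie in the same direction in each panel, with 0 in opposite directions.

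The effect of IAPP in the presence of C4BP is read from C4BP vs C4BPD under the same reading. Hmox1 rose from 260 ± 14.7 in C4BPD to 533 ± 51.5 in C4BP (SD, n = 5 each), 2.05-fold (limma, adjusted p = 2.49e-08). Jun rose 1.99-fold and Cpt1a 1.79-fold. The fatty acid binding protein Fabp3 and the oxidation enzyme Eci2 rose by 0.57 and 0.54 on the log2 scale. Nr4a1 fell from 1370 ± 161 to 688 ± 112 (log2 scale: fell by 1.00), and Vdr fell by 0.91.

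Counting all genes, 431 (2.37%) changed, 137 higher and 294 lower, 3 of them at least 2-fold. Mt1f and Mt1 rose by 0.84 and 0.74 on the log2 scale, the growth factor Bmp3 by 0.54, the dopamine receptor Drd2 by 0.52 and Uap1l1 by 0.50. The microRNA gene Mir19b2, whose dim probe set was not shown to be above background (lowest group mean 5.65 on the log2 scale), fell by 1.10, Sidt1 fell by 0.86, Cytip fell by 0.84, Dusp6 fell by 0.78, Tmem215 fell by 0.72, F3 fell by 0.71 and the calcium binding protein Calb1 fell by 0.68. Of the 614 genes changed in IAPP vs DMSO, 603 (98.2%) had the same sign here, against 65.8% of all genes tested, and the comparisons share no array. Both tests called 86 genes higher, against 1.94 expected if the calls were independent, and 169 lower, against 5.78, with 0 in opposite directions. Genes picked in 1 comparison are expected to differ less in the other by selection alone. Those higher in IAPP vs DMSO had a median difference of 0.245 there and 0.157 in C4BP vs C4BPD, and those higher in C4BP vs C4BPD had 0.241 there and 0.201 in IAPP vs DMSO. For the lower genes the medians were -0.266 and -0.204 in the first case, and -0.292 and -0.23 in the other. Likewise, 327 of the 351 genes changed in C4BPD vs DMSO (93.2%) had the same sign in C4BP vs IAPP, against 61.7% of all genes tested, with 44 higher in both, 27 lower in both and 0 in opposite directions.

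The NRF2 and metal response rose in C4BP vs C4BPD, with 7 of 16 higher, 0 lower and 9 not passing, and 10 higher adjusted over the list alone (camera adjusted p = 2.16e-12), and kept its call with an estimated correlation. Srxn1 and Osgin1 rose by 0.33 and 0.45 on the log2 scale. Immediate early genes had 2 of 30 higher, 9 lower and 19 not passing, and 4 higher and 11 lower adjusted over the list alone (camera adjusted p = 2.2e-05; adjusted p = 0.0524 with an estimated correlation). The nuclear receptors Nr4a2 and Nr4a3 fell by 0.63 and fell by 0.38. Cholesterol synthesis had 0 of 19 higher, 3 lower and 16 not passing, and 6 lower adjusted over the list alone (camera adjusted p = 3.69e-05; adjusted p = 0.102 with an estimated correlation). Hsd17b7 and Fdft1 fell by 0.37 and fell by 0.24. Fatty acid synthesis had 0 of 13 higher, 2 lower and 11 not passing, and 4 lower adjusted over the list alone (camera adjusted p = 0.000664; adjusted p = 0.0988 with an estimated correlation). ER chaperones had 0 of 24 higher, 2 lower and 22 not passing, and 2 lower adjusted over the list alone (camera adjusted p = 1.4e-05; adjusted p = 0.432 with an estimated correlation), among them Derl3 (fell by 0.45).

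In beta-cell identity and secretion, 0 of 23 were higher, 1 lower and 22 did not pass in C4BP vs C4BPD, with 2 lower adjusted over the list alone (camera adjusted p = 0.000597; adjusted p = 0.0988 with an estimated correlation). Glucose-responsive ChREBP targets had 0 of 7 higher, 2 lower and 5 not passing, and 2 lower adjusted over the list alone (camera adjusted p = 0.00757; adjusted p = 0.0988 with an estimated correlation). The arrestin family member Arrdc4 fell by 0.30 on the log2 scale. Glucocorticoid and clock genes had 1 of 17 higher, 3 lower and 13 not passing, and 1 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.0162; adjusted p = 0.0988 with an estimated correlation). The clock gene Per1 fell by 0.41, and the list lost its call without C4BPD 1 (0.0648) and with dim genes left out (0.0526). ATF4 targets had 0 of 23 past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.0773). Ins1, Ins2 and Iapp did not pass, at -0.06, -0.09 and -0.09, nor did Ddit3 (0.16), Hspa5 (-0.07) and Txnip (-0.20). The count was 223 in a fit of the compared groups alone and 200 without all arrays of number 5. Of the 37 named genes past the threshold, 8 (Msmo1, Scd2, Acly, Ero1b, Slc2a2, Pklr, Per2 and Ciart) lost their calls in 1 to 10 of the fits that each left out 1 array, at adjusted p up to 0.148, these but Scd2, and Fdft1, under another scaling or fit (up to 0.218), and 11, among them Fdft1, Derl3 and Hsd17b7, without all arrays of some number (up to 0.295).

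The single agents are set against each other in C4BPD vs IAPP. Id3 was 5.41-fold and Id1 4.15-fold higher in C4BPD (limma, n = 5 each), and Nr4a1 rose from 654 ± 80.2 in IAPP to 1370 ± 161 in C4BPD (SD). Jun fell from 965 ± 183 to 378 ± 24.5 (log2 scale: fell by 1.33; adjusted p = 5.34e-08). Atf3 fell by 1.05, Cpt1a fell by 0.78 and Hmox1 fell by 0.66 on the log2 scale. Ddit3 fell from 909 ± 98.1 to 664 ± 61.3 (adjusted p = 0.00084).

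This contrast gave 992 genes (5.46%), 662 higher and 330 lower in C4BPD, 9 of them at least 2-fold. Plekhg6, Micalcl, Calb1, Vdr, Adarb2 and Cytip rose by 1.34, 1.26, 1.14, 0.97, 0.94 and 0.90 on the log2 scale. Bmp3 fell by 0.85, Tsx fell by 0.76, Runx1t1 fell by 0.63, Uap1l1 fell by 0.61, Shc3 fell by 0.60 and Parm1 fell by 0.58. The 4 lists with calls lost them with an estimated correlation. Immediate early genes had 9 of 30 higher, 2 lower and 19 not passing, and 11 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.00141; adjusted p = 0.199 with an estimated correlation). Nr4a2, Phlda1 and Nr4a3 rose by 0.74, 0.63 and 0.48. Mitosis had 4 of 18 higher, 0 lower and 14 not passing, and 7 higher adjusted over the list alone (camera adjusted p = 4.72e-06; adjusted p = 0.31 with an estimated correlation). The NRF2 and metal response had 0 of 16 higher, 3 lower and 13 not passing, and 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.00281; adjusted p = 0.199 with an estimated correlation). Srxn1 and Osgin1 fell by 0.27 and fell by 0.40. Beta-cell identity and secretion had 1 of 23 higher, 0 lower and 22 not passing, and 4 higher adjusted over the list alone (camera adjusted p = 0.0078; adjusted p = 0.31 with an estimated correlation and 0.0717 with dim genes left out). Ins1, Ins2 and Iapp did not pass, at 0.07, 0.11 and 0.08, nor did Hspa5 (-0.04) and Txnip (-0.18). The count was 1908 with the replicate number as a block, 1529 with array weights, 753 (552 higher, 201 lower) with centred arrays, 658 without IAPP 2 and 483 without all arrays of number 2. Of the 31 named genes past the threshold, 5 (Isl1, Ttk, Cenpf, Bub1b and Ccnb1) lost their calls in 4 to 8 of the fits that each left out 1 array, at adjusted p up to 0.131, Isl1 and Bub1b also with centred arrays and in a fit of the compared groups alone, and 6, these 5 and Shc3, without all arrays of some number (up to 0.279).

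Whether the difference between IAPP and DMSO was the same with C4BP present was tested as an interaction, (C4BP minus C4BPD) minus (IAPP minus DMSO). Chac1 averaged 349 ± 39.8 in DMSO, 675 ± 52 in IAPP, 761 ± 109 in C4BPD and 799 ± 15.1 in C4BP (SD, n = 5 each). Its interaction was -0.87 on the log2 scale (limma, adjusted p = 0.00949). Slc1a4 (-0.61) and Cars1, a cysteinyl-tRNA synthetase (-0.45), gave adjusted p = 0.0118 each. Trib3 (-1.0), Iars1, an isoleucyl-tRNA synthetase (-0.34), and Stap2 (-0.46) gave 0.0221, and the autophagy protein Wipi1 (-0.37) gave 0.0229. Klf6 (-0.39) and Plppr1 (-0.38) also passed, and Mt1f (-0.58) did not (adjusted p = 0.0536).

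In total 9 genes passed, 0 higher and 9 lower. ATF4 targets had 0 of 23 higher, 2 lower and 21 not passing in the interaction, and 11 lower adjusted over the list alone (camera adjusted p = 1.67e-19), with a mean of -0.22, and kept the call with an estimated correlation (adjusted p = 0.000375). Aars1 and Psat1, at -0.25 and -0.29, did not pass over all genes. Calls of 4 other lists were lost with an estimated correlation. Cholesterol synthesis had 0 of 19 past the threshold and 0 adjusted over the list alone (camera adjusted p = 5.62e-06; adjusted p = 0.2 with an estimated correlation), with a mean of 0.098. ER chaperones had 0 of 24 in both counts and a mean of 0.08 (camera adjusted p = 0.00163; adjusted p = 0.648 with an estimated correlation). Immediate early genes had 0 of 30 higher, 1 lower and 29 not passing, and 5 lower adjusted over the list alone (camera adjusted p = 0.00351; adjusted p = 0.225 with an estimated correlation). Acinar and duct markers had 0 of 13 in both counts and a mean of 0.089 (camera adjusted p = 0.0398, and 0.584 with an estimated correlation and 0.0592 with quantile normalization). Their call was also lost with the replicate number as a fixed block. Ins1, Ins2, Iapp, Hspa5, Ddit3 and Txnip did not pass, at -0.02, 0.05, -0.01, 0.03, -0.30 and -0.30. The count was 14 with trend and robust options and 0 over all 36495 probe sets (limma; 1405 at an unadjusted p under 0.05), 0 without all arrays of number 1, 3, 4 or 5, and 3 to 5 without any 1 of 10 single arrays. The 1405 is under the share of 0.05 that chance alone would give at that p. Of the 9 genes, 6 (Iars1, Stap2, Trib3, Wipi1, Klf6 and Plppr1) lost their calls in 7 to 18 of the fits that each left out 1 array, at adjusted p up to 0.114, and so did the lists of ER chaperones (without DMSO 3, 0.126, or C4BP 3, 0.0735), immediate early genes (without C4BPD 1, 0.0689) and acinar markers (in 9 such fits).

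**Figure D4:**
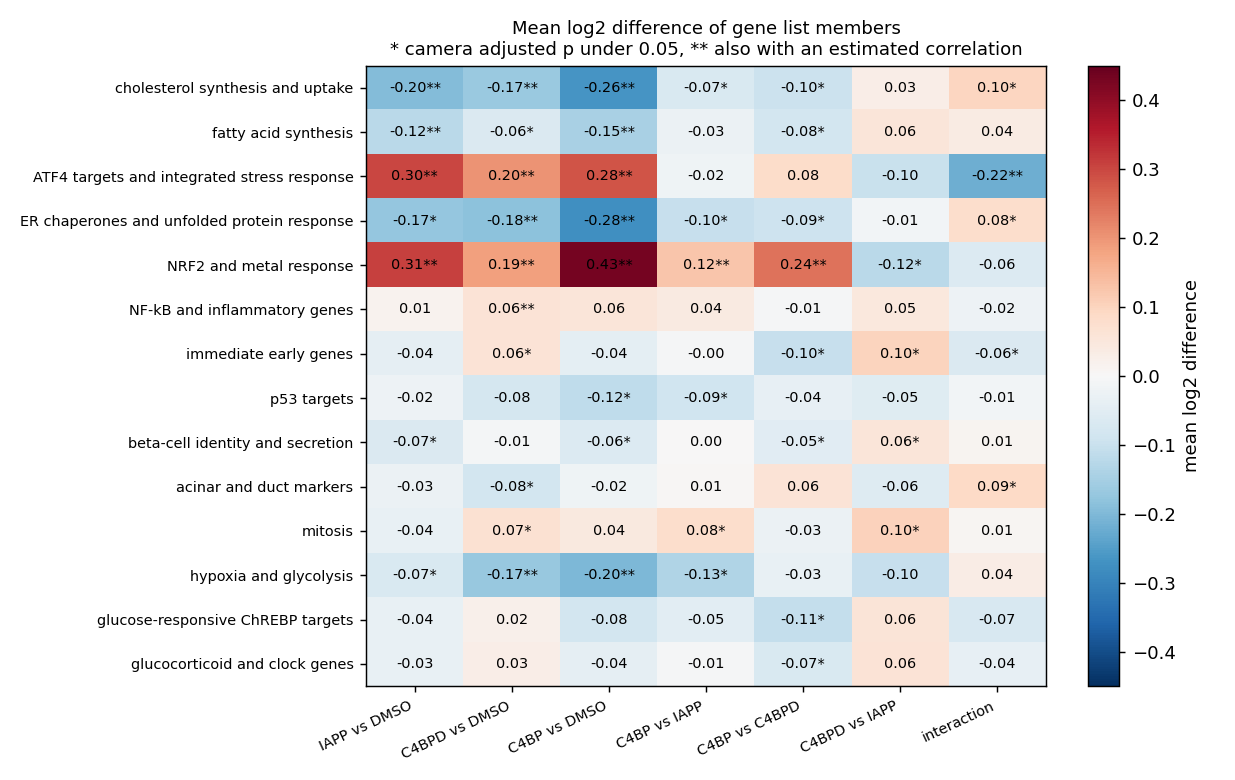
Mean log2 difference of the measured members of each gene list with a call (rows) in each comparison (columns, the last being the interaction); 1 star marks a camera adjusted p under 0.05 and 2 stars one that also holds with an estimated correlation. ATF4 targets averaged 0.302 in IAPP vs DMSO and -0.22 in the interaction.

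Of the 31 lists tested, 17 had no camera call in any of the 6 comparisons. Ribosomal proteins (56 measured) averaged between -0.004 and 0.004 on the log2 scale. The proteasome (24) averaged -0.019 to 0.019, nuclear oxidative phosphorylation genes (24) -0.033 to 0.036, cytosolic heat shock genes (13) -0.019 to 0.004 and DNA replication genes (20) -0.039 to -0.003. The apoptosis machinery (18) averaged -0.03 to 0.021, autophagy and lysosome genes (20) -0.008 to 0.044, sterol efflux and LXR targets (10) -0.03 to 0.035, and SRF and YAP targets (13) -0.069 to 0.063. Amylin receptor and amyloid degradation genes (11) averaged -0.047 to 0.023, complement genes (12) -0.036 to 0.032 and interferon response genes (17) -0.053 to 0.062. Markers of other cell types were also without calls, with leukocyte markers (11) at -0.029 to 0.032, fibroblast and stellate cell markers (12) at -0.061 to 0.059 and other islet cell markers (10) at -0.024 to 0.042. MicroRNA genes (363) averaged -0.025 to 0.027 and olfactory receptors (1157) -0.025 to 0.03. The smallest camera adjusted p among these lists was 0.054, for autophagy and lysosome genes. Summed over the 6 comparisons, members past the threshold numbered 18 in autophagy and lysosome (25 adjusted over the list alone), 9 in the apoptosis machinery (12), 5 in the amylin receptor list (14), 6 in sterol efflux (10), 28 among olfactory receptors (2), 13 among microRNAs (4), and 4 or fewer in each other list.

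Fry, which compares a list with no other genes, passed 37 of the 48 list calls. The 11 it did not pass, all of them also lost with an estimated correlation, were mitosis (fry adjusted p = 0.0585) and acinar markers (0.156) in C4BPD vs DMSO, cholesterol synthesis, ER chaperones, p53 targets and mitosis in C4BP vs IAPP (0.0575 each), ER chaperones in C4BP vs C4BPD (0.0898), and in the interaction cholesterol synthesis (0.13) and ER chaperones, immediate early genes and acinar markers (0.538 each). Fry also passed lists without a camera call in 15 cases. Autophagy and lysosome genes were among them, higher in IAPP vs DMSO (fry adjusted p = 0.00125), C4BPD vs DMSO (0.0182) and C4BP vs DMSO (0.000131), as were amylin receptor and amyloid degradation genes, lower in IAPP vs DMSO (0.0391) and C4BP vs DMSO (0.046), and SRF and YAP targets, lower in C4BPD vs IAPP (0.0455). The other 9 were immediate early genes in IAPP vs DMSO (0.0391), p53 targets in C4BPD vs DMSO (0.0406), NF-kB genes (0.0282) and ChREBP targets (0.046) in C4BP vs DMSO, and in C4BPD vs IAPP fatty acid synthesis (0.0414), NF-kB genes (0.0461), hypoxia and glycolysis (0.0354), ChREBP targets (0.0304) and glucocorticoid and clock genes (0.0139).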

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

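The regroupings of the arrays and the permutations of residuals were the tests chosen only after the result was seen. The genes Chac1, Slc1a4, Cars1, Iars1, Stap2, Trib3, Wipi1, Klf6 and Plppr1 stood out because their difference between IAPP and DMSO wells was not the same as that between C4BP and C4BPD wells. Their interactions, on the log2 scale, were -0.87 for Chac1, -0.61 for Slc1a4, -0.45 for Cars1, -0.34 for Iars1, -0.46 for Stap2, -1.0 for Trib3, -0.37 for Wipi1, -0.39 for Klf6 and -0.38 for Plppr1. Of 100 groupings of the 20 arrays, 2 gave at least as many genes as the real one (9), the real one included. The highest other gave 50, several times the real count. Such groupings mix the additive effects of the treatments into the spread and the contrast, so chance was not excluded from them. With the additive effects kept and their residuals permuted, 1 of 100 permutations, the real one, gave as many genes. The highest other gave 0 (1 with permutations within a replicate number), which argues against chance at this share. Regroupings within replicate numbers, which also mix in the additive effects, came closer. Of 100, the real one gave 9 genes and the highest other 6 (18 and 13 with the number as a block). The count still depends on the arrays, and was 0 without all arrays of number 1, 3, 4 or 5 (limma; 816, 718, 692 and 524 at an unadjusted p under 0.05). Chance alone would bring a share of 0.05 of the genes under that p, more than any of these counts or the 688 with all 20 arrays. Centring arrays on their median ended the calls of Cars1, Iars1, Wipi1 and Plppr1, and quantile normalization those of Klf6 and Plppr1.

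The list of ATF4 targets and integrated stress response genes had a mean interaction of -0.22. Of its 23 measured members, 2 passed the interaction and 21 did not, so this mean is mostly over genes outside the 9. A single deviating array is argued against, since the list stayed past the threshold in 20 of 20 fits that each left out 1 array. The highest camera adjusted p was 1.21e-14, at the preset correlation. These fits were not run with an estimated correlation. A ceiling of the array signal is argued against too, because the median of the members' highest group means lay 2.99 log2 units below the 99th percentile of all genes. The list averaged 9.867 in DMSO, 10.17 in IAPP, 10.07 in C4BPD and 10.15 in C4BP on the log2 scale. The smaller difference between C4BP and C4BPD thus goes with a higher level in C4BPD than in DMSO. A lower level in C4BP than in IAPP was not detected (camera adjusted p = 0.99). Why the levels lay this way was not tested, and these arrays hold 1 dose and 1 time.

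A sample far from the others of its group was found for 2 of 60 groups tested, where chance gives about 1 in 20. DMSO 1 had a log2 intensity of 12.79 for Ins1, against 12.45 to 12.52 in the other DMSO arrays. C4BPD 3 had 11.31 for Txnip, against 11.57 to 11.64 in the other C4BPD arrays.

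Signal in data outside the comparisons came from 17984 probe sets without a single gene symbol. Of these, 67 changed in IAPP vs DMSO, 9 in C4BPD vs DMSO and 49 in C4BP vs DMSO (limma, adjusted over these probe sets). Between the other groups, 58 changed in C4BPD vs IAPP, 16 in C4BP vs C4BPD and 7 in C4BP vs IAPP.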

How the results depend on the processing

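No alternative was chosen after the data were seen. Over 9300 alternative values of named genes and called lists, 8450 kept their sign and their side of the threshold, 645 were no longer past it, 151 newly passed and 54 changed sign, 0 of these past the threshold as reported. With the replicate number as a fixed block, the counts were 1133 in IAPP vs DMSO, 797 in C4BPD vs DMSO, 1884 in C4BP vs DMSO, 352 in C4BP vs IAPP, 958 in C4BP vs C4BPD and 1908 in C4BPD vs IAPP, 18 for the interaction and 2604 by the F test. As a random block (consensus correlation 0.21) they were 984, 672, 1680, 290, 820, 1676, 16 and 2347. All 614 genes of IAPP vs DMSO stayed past the threshold with the fixed block. By the labels, wells of 1 number share that number and a run of array numbers. The run is 1 to 4 for number 1 and 17 to 20 for number 5. The data hint at more. After removal of the group means, wells of 1 number correlated over 0.1 in 20 of 30 pairs, with a median of 0.169. The value for different numbers, -0.044, is no separate comparison, since the deviations within a group sum to 0. Of the 30 pairs, 17 correlated best with their own number. The number took 78.9% of the variance of principal component 2. Within each run of array numbers the titles come in the order IAPP, C4BP, C4BPD and DMSO. Treatment and place in the run therefore cannot be told apart. In C4BPD vs IAPP the fixed block added calls of Mt1, Kcnj11, Slc2a2 and Scg2 and changed no other call of a named gene or list. Array medians set to 0 gave 223 in C4BPD vs DMSO and 70 in C4BP vs IAPP; neither this nor quantile normalization moved the median of all genes by over 0.00984. Leaving out dim genes gave 200 in C4BP vs IAPP, over 11217 genes. Trend and robust options gave 14 for the interaction, and array weights 644 in C4BPD vs DMSO and 1529 in C4BPD vs IAPP. With all 36495 probe sets the counts were 226 in C4BPD vs DMSO, 70 in C4BP vs IAPP and 0 for the interaction (limma; 1405 at an unadjusted p under 0.05), where more tests are adjusted for. The 1405 is under the share of 0.05 that chance alone would give. A fit of the compared groups alone, with fewer samples behind the spread, gave 208 in C4BPD vs DMSO, 663 in C4BP vs DMSO, 33 in C4BP vs IAPP and 223 in C4BP vs C4BPD. Grouping by the treatment field gave 0 genes in all 6 comparisons, the interaction and the F test (limma; 707, 881, 653, 553, 639, 426, 929 and 549 at an unadjusted p under 0.05). The other reading of the titles gave 1377 for the interaction, 812 higher and 565 lower. Its contrast is (C4BPD minus C4BP) minus (IAPP minus DMSO), which adds up 2 differences that mostly share a sign. Differences near 0 changed sign: Ddit3 in C4BPD vs DMSO was -0.013 with quantile normalization and -0.013 with array weights, which also gave -0.001 for Iapp in C4BPD vs DMSO, 0.005 for Ins2 in C4BP vs C4BPD and 0.002 for the Ins1 interaction. Other than for the construction named, the cause was not tested.

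Leaving out 1 array, or all 4 of a number, gave 235 to 584 genes in IAPP vs DMSO, 151 to 386 in C4BPD vs DMSO, 615 to 1059 in C4BP vs DMSO, 18 to 97 in C4BP vs IAPP, 200 to 522 in C4BP vs C4BPD, 483 to 1006 in C4BPD vs IAPP, 0 to 10 for the interaction and 716 to 1583 by the F test. Counts moved over 1.5 times without IAPP 4 (405 in IAPP vs DMSO), DMSO 5 (233), C4BPD 2 (230) or C4BPD 5 (217) in C4BPD vs DMSO, and IAPP 2 in C4BPD vs IAPP (658). In C4BP vs IAPP this held for IAPP 2 (66), IAPP 3 (58), IAPP 4 (67), C4BP 4 (64) and C4BP 5 (73). For the interaction it held for DMSO 1 (5), DMSO 2 (4), IAPP 2 (4), IAPP 3 (4), C4BPD 2 (4), C4BPD 3 (4), C4BPD 4 (5), C4BPD 5 (3), C4BP 3 (3) and C4BP 4 (4). The interaction fell to 0 without all arrays of number 1, 3, 4 or 5 (limma; 816, 718, 692 and 524 at an unadjusted p under 0.05). These unadjusted counts are under the share of 0.05 that chance alone would give. Fixed genes that changed sign ranged, in C4BPD vs DMSO, from -0.043 to 0.044 for Ddit3, -0.018 to 0.02 for Iapp, -0.041 to 0.089 for Ins1 and -0.138 to 0.033 for Ins2. In C4BP vs IAPP, Iapp ranged from -0.04 to 0.015, Ins1 from -0.042 to 0.03 and Ins2 from -0.022 to 0.056. In C4BP vs C4BPD, Ins1 ranged from -0.143 to 0.004 and Ins2 from -0.154 to 0.018. Ins1 ranged from -0.108 to 0.025 in C4BP vs DMSO and from -0.075 to 0.02 in IAPP vs DMSO. Interactions ranged from -0.043 to 0.013 for Iapp, -0.084 to 0.046 for Ins1 and -0.009 to 0.161 for Ins2. The cause was not tested.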

Other observations

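The regroupings of the arrays, the tests of the sample labels and the exact permutation tests of lists were chosen only after the result was seen. Some differences in comparisons where the rule did not name the gene are given here, and were chosen after their values were seen. In IAPP vs DMSO, Hrk, a pro-death member of the BCL2 family, rose by 0.56 on the log2 scale (limma, adjusted p = 1.5e-05), and Cflar, an inhibitor of death-receptor signalling, fell by 0.33. In C4BP vs DMSO, Hrk rose by 0.42 and Cflar fell by 0.47. In C4BPD vs IAPP, Hrk fell by 0.38. The cholesterol exporter Npc1 of the lysosome rose by 0.31 in IAPP vs DMSO and by 0.24 in C4BP vs DMSO. Ramp1, a subunit of amylin receptors, fell by 0.21 and fell by 0.33 in the same comparisons, and the chemokine Cxcl10 rose by 0.38 and 0.48. The clock genes Per1 and Per2 rose by 0.36 and 0.30 in C4BPD vs IAPP. The difference between C4BP vs DMSO and IAPP vs DMSO is C4BP vs IAPP, which was tested over all genes. Other differences among these comparisons were not tested beyond the interaction.

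A few members of the SMAD pathway, picked after their values were seen, differed between wells with and without a C4BP title, while the 17 members not picked did not pass as a list. Bambi, a decoy receptor of the BMP and TGF-beta pathway, rose by 0.62 on the log2 scale in C4BPD vs DMSO and by 0.35 in C4BP vs IAPP. Smad9 rose by 0.59 and 0.53, Smad7 by 0.76 and 0.32, and Acvr1c by 0.68 and 0.63. Id4 rose by 0.49 in C4BP vs IAPP and did not pass in C4BPD vs DMSO, at 0.29 (adjusted p = 0.0571).

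The rise of Id1 and Id3 with both C4BP titles was weighed first. A few deviating arrays are argued against, since 10 of 10 arrays with a C4BP title lay above all 10 others for both genes. A SMAD-pathway response may be the cause, since Id1 and Id3 are known targets, but a difference of the 17 members not yet looked at was not detected in C4BPD vs DMSO (mean -0.00811, camera p = 0.983, exact permutation p = 0.897) or C4BP vs IAPP (camera p = 0.552, exact permutation p = 0.556). Of these 17, Atoh8 rose, by 0.34 and 0.35, and the other members did not pass in either comparison. The members whose values had been seen, Id1 and Id3 among them, were not in this list. The test therefore leaves the explanation open. A factor carried along in the C4BP preparation cannot be told apart from C4BP itself, since 0 preparations that differ between wells are named in the labels.

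The conflict between titles and treatment field was weighed next. That the treatment field gives the true treatments is argued against, since it gave 0 genes by the F test (limma; 549 at an unadjusted p under 0.05), against 1426 for the titles. The reading of C4BP wells as holding IAPP, and C4BPD wells as lacking it, had the values it needs: 98.2% of the 614 genes changed in IAPP vs DMSO moved the same way in C4BP vs C4BPD, against 65.8% of all genes.

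Chance is argued against for each comparison at this share, as 1 of 100 splits of the arrays, the real one, gave as many genes. These splits ignore the replicate numbers and mix the treatment difference into the spread, so chance is not excluded. The real count and the highest other were 614 and 2 in IAPP vs DMSO, 351 and 1 in C4BPD vs DMSO, 1082 and 1 in C4BP vs DMSO, 110 and 17 in C4BP vs IAPP, 431 and 8 in C4BP vs C4BPD, 992 and 1 in C4BPD vs IAPP, and 1426 and 1 by the F test. In each comparison of 2 groups, 16 splits part all 5 numbered pairs, too few for a share under 0.05, and the real one gave the most genes. In C4BPD vs IAPP it gave 992 genes against 1 in the highest other (1908 against 1 with the block).

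Cpt1a, Eci2 and Fabp3, all of fatty acid use, were higher in wells with IAPP, which led to the hypothesis of a response of PPAR target genes. A list of 28 such genes not yet looked at, 26 of them measured, was written before its test. It was higher in IAPP vs DMSO, with a mean of 0.0583 and 4 genes higher (camera p = 0.0197, exact permutation p = 0.00794), and in C4BP vs C4BPD, with a mean of 0.0656 and 2 genes higher (camera p = 0.0235, exact permutation p = 0.00794). The last is the smallest p that the 252 splits of 10 arrays can give, and in both comparisons all 5 arrays with IAPP lay above the 5 others. In C4BPD vs DMSO the list did not pass (camera p = 0.805, exact permutation p = 0.532). C4BPD vs IAPP gave a mean of -0.0561 with 3 genes lower, and did not pass camera (p = 0.0589, exact permutation p = 0.0159). Most members did not pass, 22 of 26 in IAPP vs DMSO and 24 of 26 in C4BP vs C4BPD. Pdk4 and Angptl4 were among them, at 0.08 and 0.07 in IAPP vs DMSO and 0.11 and 0.12 in C4BP vs C4BPD. The mitochondrial genes Acaa2 and Slc25a20 rose by 0.45 and 0.37 in IAPP vs DMSO and by 0.49 and 0.37 in C4BP vs C4BPD. Other members lay below 0 without passing. Hadha, Hadhb, Decr1 and Eci1 were at -0.11, -0.14, -0.10 and -0.11 in IAPP vs DMSO. In C4BP vs C4BPD they were at -0.10, -0.15, -0.22 and -0.08. In C4BP vs DMSO the list had a mean of 0.0678, with 5 genes higher and 1, Hadhb, lower (camera p = 0.0466, exact permutation p = 0.00794). A higher list mean is what a PPAR response to IAPP would give. That response remains a hypothesis, since members went both ways and it began from genes of the same arrays.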
